A study of Mus musculus with 4 samples.

How the data were processed

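RNA was measured in 4 libraries, 2 per genotype, from B220+CD43+ cells sorted from mouse bone marrow, each from a pool of 2 mice. Per the labels' protocols, RNA was extracted with Trizol, and libraries were made from polyadenylated RNA with an Illumina TruSeq RNA kit. Whether the kit kept strand is not given in the sources used here. Samples were grouped by the genotype in the labels.

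Per the submitters' processing notes, reads were processed with Trimmomatic 0.32, TopHat2 2.0.11 and Cuffdiff 2.1.1 against the mm10 build. Their options, the gene annotation and the scaling between libraries are not given in the sources used here. The deposited table holds, per the file headers, 1 FPKM value per gene and genotype, which combines the 2 libraries of a genotype. The deposited table also gives Cuffdiff's test statistic, a score on which no fold change was based here. The authors' p-value and q-value stand beside it. The q-value equals a Benjamini-Hochberg adjustment of the p-value over the tested entries, with a largest difference of 5.27e-07. The smallest deposited p-value was 5e-05, shared by 396 genes, so genes with q = 0.0016 cannot be ranked by it. No value per library was used, so no spread between libraries is given, and p-values rest on the authors' model of 2 libraries per genotype.

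Of 23275 entries, 12683 were tested by the authors. Of the rest, 10441 were marked as not tested, 147 as having too little data and 4 as failed. Fold changes were computed from the FPKM values, because 688 cells of the deposited fold change column held a spreadsheet error where the Hdac3-deleted value was 0. Spreadsheet software had also turned 25 gene names into dates, and 1 of these was called. The depth of the libraries is unknown. The commonest ratio of Hdac3-deleted to wild-type values, 1.14 in 78 entries within 0.0005 log2 units, hints that 1 fragment was worth 1.14 times more in the Hdac3-deleted group. Among tested entries, 2478 shared their locus with another entry, of which 78 were called. Among them were Serpina3f, Rag2, Cd72, Egfl7, Ms4a1, Hdac7, Scd2 and Il1b, whose values below are less certain for this reason.

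A gene was called changed at the authors' q-value under 0.05. Before the data were examined, 29 gene lists were fixed, together with the tests and the rule for genes named in the text. That rule took Hdac3, the 10 genes with the largest increase and the 10 with the largest decrease among called genes with at least 5 FPKM in 1 genotype, and up to 4 called members of each list by smallest q, with ties broken by fold. Where no member was called it took up to 2 members with the highest mean, and any called member of the first 7 lists could be named. Genes outside the rule were chosen after their values were seen. 25 lists had tested members, and 4 lists had no entries used here, namely mitochondrially encoded genes, the DJ-proximal and the DJ-distal heavy chain V genes, and kappa V genes. Older gene symbols were matched through the reference annotation.

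For each list the median log2 fold change was placed as a percentile among 10000 random lists of the same size, matched on expression in 10 bins, as a description and not a p-value. Enrichment among higher and among lower genes was tested against all other tested genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 50 tests. Genes are not independent replicates in these tests. Lower bounds of 6 genes used the log2 fold change over the authors' test statistic as the standard error and a normal quantile of 4.61, a 95% interval adjusted over all tested genes. Positions follow the deposited table, shifted to count from 1, and exon overlaps come from a reference annotation of the same build. The list statistics were tested on simulated data for this comparison with 12643 genes, 200 of them changed by 1 log2 unit. A list of 25 genes, all raised by 1 log2 unit, passed in 20 of 20 runs by both statistics. An unchanged list, drawn only from unchanged genes, fell outside the middle 95% in 1 of 20 runs and passed Fisher's test in 0. Simulated genes varied independently. These runs do not show how lists of genes that vary together, or lists with smaller shifts, would fare. The simulated calls recovered 33.5% of the changed genes, under an assumed spread.

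Alternatives varied the q threshold, a minimum fold change, a minimum of 1 FPKM, a pseudocount of 1 FPKM, centring on the median gene, and entries with 1 symbol. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.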

Results

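Polyadenylated RNA was sequenced from B220+CD43+ cells sorted from the bone marrow of 8-week-old mice. This surface phenotype marks early B-lineage cells in marrow. In 2 libraries the Hdac3 gene had been deleted with Mb1-cre, a recombinase expressed from the early B-cell stage onward, in mice carrying 1 conditional and 1 null allele. The other 2 libraries came from mice with intact Hdac3 that carried the same recombinase, called wild-type here. Each library pooled cells from 2 mice. Histone deacetylase 3 is the catalytic subunit of the NCoR/SMRT corepressor complexes, and the study asked what its loss does to B-cell development and V(D)J recombination. All levels below are the authors' group values in FPKM, fragments per kilobase of transcript scaled to the size of the library, 1 value per genotype with no replicate spread, and fold changes were computed from them. The depth of each library is unknown.

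Hdac3 itself, on chromosome 18 from position 37936971 to 37954988 of the mm10 build, was 46.8 FPKM in wild-type cells and 22.0 FPKM in Hdac3-deleted cells, 47.1% of the wild-type level. The authors' deposited table gives q = 0.0016 for this difference. The value covers the whole gene, so fragments from exons outside the deleted part count toward it, as do those of any sorted cells that do not express Mb1-cre. In the Hdac3-deleted group such cells would still carry the null allele, so they too may differ from wild-type cells in Hdac3 dose. Transcripts typical of cells outside the B lineage were abundant in both genotypes, such as Siglech at 420 and 590 FPKM, and "Hdac3-deleted cells" below means the whole sorted population.

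Loss of Hdac3 was accompanied by higher transcripts of the recombinase genes and of some early progenitor genes, and by lower transcripts of some mitotic, immediate early and myeloid genes. Rag1, a catalytic subunit of the V(D)J recombinase, rose 4.77-fold from 77.8 to 372 FPKM. Fos, an immediate early transcription factor, fell 8.37-fold from 31.3 to 3.74 FPKM. Of 12683 genes tested, 881 changed in the authors' deposited table at a q under 0.05, or 6.95%, with 356 higher and 525 lower in Hdac3-deleted cells. At least a 2-fold difference was seen for 130 of the higher and 296 of the lower genes. The median log2 fold change of the 11116 genes with at least 1 FPKM in both genotypes was 0.02. A normal approximation to the authors' test statistic called fewer genes, 136 higher and 335 lower.

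**Figure D1:**
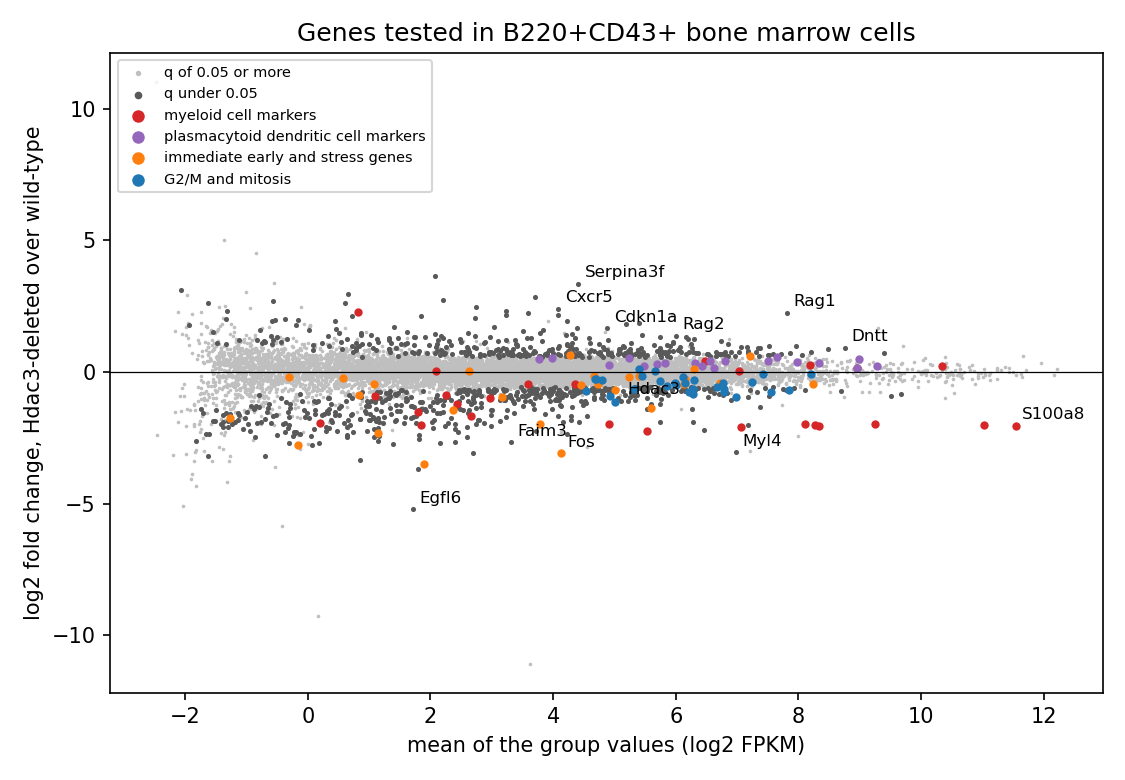
Log2 fold change of Hdac3-deleted over wild-type cells against the log2 mean of both group values in FPKM, 1 point per tested gene with a value above 0 in both genotypes. Dark grey points have a deposited q under 0.05, and coloured points are members of 4 gene lists; most myeloid markers lie far below 0, and Rag1 and Dntt lie above 0 at high levels.

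Among genes with at least 5 FPKM in 1 genotype, the 10 with the largest increases were led by the secreted protease inhibitors Serpina3n and Serpina3f. Serpina3n rose 12.5-fold from 0.62 to 7.80 FPKM, and Serpina3f 10.3-fold to 38.8 FPKM. With a pseudocount of 1 FPKM the order changed to Serpina3f at 3.06, Crhbp at 2.52 and Serpina3n at 2.44 on the log2 scale. Serpina3f shares its locus with another entry of the table, so its value is less certain. Without the pseudocount, Serpina3n and Serpina3f were followed by Crhbp at 7.26-fold, Rapgef4 at 6.71-fold, Pygm at 5.53-fold and Cxcr5 at 5.33-fold. Next came Cish at 5.05-fold, Rag1, Fam70a at 4.73-fold and Prelid2 at 4.55-fold. Cxcr5, a chemokine receptor of B-cell follicles, went from 5.37 to 28.6 FPKM. Its exons overlap those of the opposite-strand gene Bcl9l, which itself rose 1.82-fold. The largest decrease without a pseudocount was that of Egfl6, from 6.41 to 0.17 FPKM. With a pseudocount of 1 FPKM its log2 fold change was -2.66, behind Myl4 at -3.00 and Fos at -2.77. Cldn10 fell 12.9-fold, Fosb 11.4-fold, Fos 8.37-fold, Myl4 8.25-fold, Mmp14 6.50-fold, Faim3 6.27-fold, Mcpt8 6.22-fold, Pfn2 5.88-fold and Trib2 5.59-fold. Myl4, a myosin light chain, was the most abundant of these, at 227 FPKM in wild-type and 27.5 FPKM in Hdac3-deleted cells. Faim3, the receptor for the Fc part of IgM, went from 17.1 to 2.73 FPKM.

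The V(D)J recombination list held 20 tested genes, of which 3 rose and 1 fell. Rag2, the partner of Rag1, rose 2.60-fold from 35.5 to 92.3 FPKM. Dntt, the polymerase that adds nucleotides at the joints, rose 1.91-fold from 298 to 569 FPKM. Polm, a polymerase of end joining, fell 1.56-fold to 12.0 FPKM. Adjusted over the list alone, 4 genes were higher and 6 lower. The list's median log2 fold change was -0.02, at percentile 32.8 of 10000 random lists matched on expression. Its enrichment among higher genes did not pass (Fisher's exact test, adjusted p = 0.0675), but at a q threshold of 0.01 the adjusted p was 0.0193. Exons of Rag1 and Rag2 overlap those of B230118H07Rik on chromosome 2, which was 4.23 and 4.89 FPKM. The immunoglobulin locus architecture list, with cohesin and Polycomb members, had 16 tested genes and a median of -0.13, and Pax5 was its 1 higher gene.

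B-lineage transcription factors had 26 tested members, of which 5 rose and 1 fell, both over all genes and adjusted over the list alone. Sox4 rose 2.37-fold from 43.6 to 103 FPKM, Lef1 2.37-fold from 46.6 to 110 FPKM and Erg 2.22-fold from 38.4 to 85.2 FPKM. Foxo1, an activator of the Rag genes, rose 2.03-fold from 38.3 to 77.6 FPKM, and Pax5, the B-lineage commitment factor, 1.52-fold from 79.7 to 121 FPKM. Gfi1 fell 1.57-fold to 5.98 FPKM. The median log2 fold change was 0.32, above all matched random lists, and the list was enriched among higher genes (Fisher's exact test, adjusted p = 0.00571). Plasmacytoid dendritic cell markers had a median of 0.34 in the same samples, so a median of this size was not restricted to B-lineage genes.

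Of 23 tested genes of pre-B-cell receptor and B-cell receptor signalling, 5 rose and 3 fell. The surrogate light chain genes Igll1 and Vpreb1 rose 1.64-fold to 834 FPKM and 1.57-fold to 327 FPKM. The adaptors Blnk and Pik3ap1 rose 1.68-fold and 1.87-fold, and the kinase subunit Pik3cd 1.60-fold. Bank1 fell 2.66-fold, the inhibitory receptor Cd72 1.92-fold from 191 to 99.5 FPKM, and the kinase Blk 1.59-fold. Adjusted over the list alone, 5 were higher and 4 lower. The list was enriched among higher genes (Fisher's exact test, adjusted p = 0.00376), but at a q threshold of 0.01 the adjusted p was 0.769. Exons of Vpreb1 overlap Top3b and those of Cd72 overlap Tesk1.

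Stem and early lymphoid progenitor genes had 20 tested members, 4 higher and 2 lower, with a median log2 fold change of 0.40. Kit, the stem cell factor receptor, rose 4.54-fold from 6.13 to 27.8 FPKM. Egfl7 rose 2.16-fold, Hoxa9 2.07-fold and Meis1 1.71-fold, while Gfi1b fell 3.27-fold and Gata2 2.90-fold from 0.587 to 0.202 FPKM. With a pseudocount of 1 FPKM the log2 fold change of Gata2 went from -1.54 to -0.40. There were 7 higher and 3 lower genes adjusted over the list alone, and the list was enriched among higher genes (Fisher's exact test, adjusted p = 0.0148). In the interleukin 7 receptor and STAT5 list, Cish rose from 3.10 to 15.7 FPKM and Socs2 2.31-fold to 41.3 FPKM, both being feedback inhibitors induced by STAT5. No other of its 17 tested genes changed, its median was 0.32, and its enrichment did not pass (Fisher's exact test, adjusted p = 0.229). In the same samples the medians of plasmacytoid dendritic cell markers and of T, NK and innate lymphoid markers were 0.34 and 0.24.

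Genes of the late pre-B and immature B cell moved both ways, with 4 higher and 5 lower of 25 tested. Cxcr5 rose, as did Ltb 1.78-fold, Cd40 2.06-fold and S1pr1 1.61-fold. Faim3 fell, as did Cr2 5.17-fold from 0.546 to 0.106 FPKM, Fcer2a 3.70-fold, Ms4a1 2.49-fold from 28.3 to 11.3 FPKM, and Il2ra 2.30-fold from 8.82 to 3.84 FPKM. With a pseudocount of 1 FPKM the log2 fold change of Cr2 went from -2.37 to -0.48. Ms4a1, which shares its locus with another entry, encodes CD20, and Il2ra encodes CD25, a marker of small pre-B cells. Adjusted over the list alone, 5 were higher and 5 lower. The median log2 fold change was 0.20 and the mean -0.07. Enrichment passed in both directions (Fisher's exact test, adjusted p = 0.0269 for higher and 0.0199 for lower genes), and for lower genes it was 0.0751 with genes of at least 1 FPKM alone. Plasma cell markers included 3 lower genes of 12, namely Igj, down 2.54-fold from 239 to 93.9 FPKM, Sdc1 at 1.76-fold and Derl3 at 2.08-fold (Fisher's exact test, adjusted p = 0.0533).

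**Figure D2:**
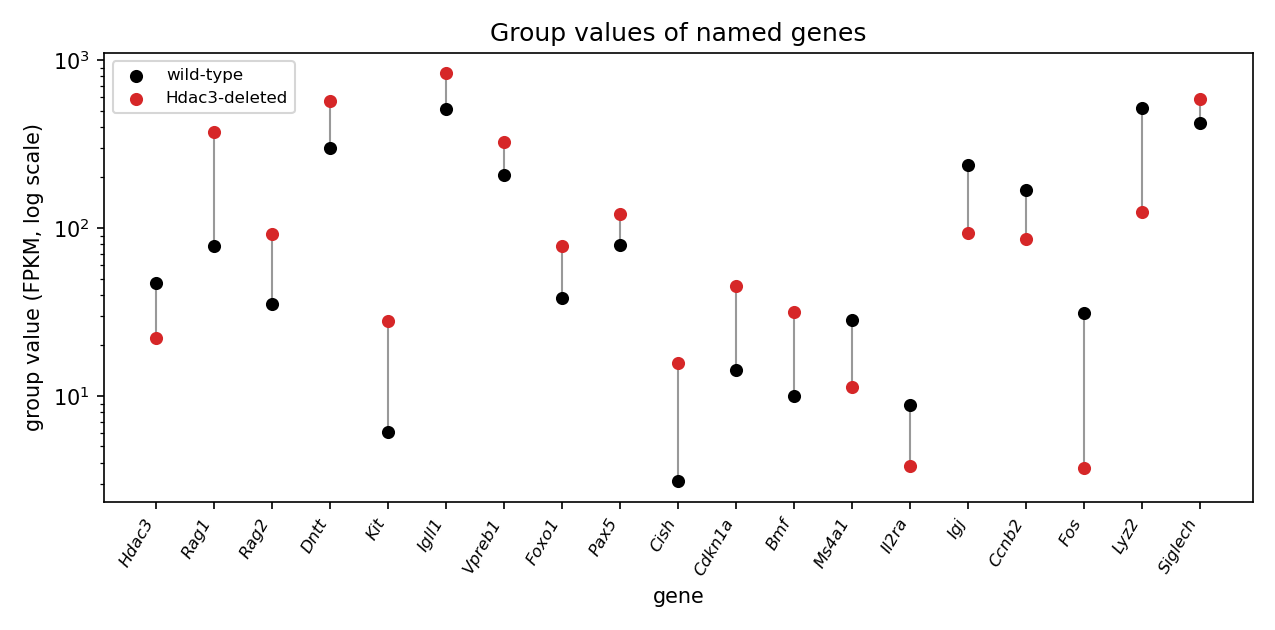
Group values in FPKM on a log scale for 19 named genes, with wild-type in black and Hdac3-deleted in red and a line joining the 2 values of a gene; no replicate spread can be drawn. Rag1, Kit and Cish lie several-fold higher in Hdac3-deleted cells, and Fos and Lyz2 several-fold lower.

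Of 30 tested genes of G2/M and mitosis, 12 fell and 0 rose, and 28 had negative fold changes. Nek2 fell 2.21-fold, cyclin Ccnb2 1.94-fold from 168 to 86.5 FPKM, the checkpoint kinase Bub1 1.87-fold and Mad2l1 1.79-fold. The median log2 fold change was -0.46, below all matched random lists, and the list was enriched among lower genes (Fisher's exact test, adjusted p = 2.44e-08). The count adjusted over the list alone was 15 lower genes. Myeloid markers, with 14 of 26 lower, and 3 of 12 plasma cell markers fell in the same samples. Of 29 tested genes of G1/S and DNA replication, 4 fell, and 29 had negative fold changes with a median of -0.40. Rfc3 fell 1.65-fold, Rrm2 1.60-fold from 275 to 172 FPKM and Mcm5 1.53-fold, and Pola1 fell by 0.59 on the log2 scale. Adjusted over the list alone, 6 fell, and enrichment did not pass (Fisher's exact test, adjusted p = 0.108). Glycolysis genes had a median of -0.28 with Slc16a3 the 1 lower gene of 17. Replication-dependent histones, measured here only in polyadenylated RNA, had a median of -0.13 with Hist1h2bg and Hist1h1c lower among 35.

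Genes of the p53 and DNA damage list were enriched among higher genes (Fisher's exact test, adjusted p = 0.000514), with 6 higher and 1 lower of 24 tested. Cdkn1a, the cell-cycle inhibitor p21, rose 3.16-fold from 14.2 to 44.9 FPKM. The pro-apoptotic Bbc3 rose 2.09-fold, Sesn1 1.72-fold and Ddit4 1.67-fold, and adjusted over the list alone 6 were higher and 2 lower. Fas fell 2.31-fold from 2.76 to 1.20 FPKM, and Mdm2, Ccng1, Zmat3, Aen and Bax did not pass the test. The median was 0.08, at percentile 74.1 of matched random lists. In the BCL2 family, Bmf, another pro-apoptotic member, rose 3.18-fold to 31.8 FPKM, and with Bbc3 it was 1 of 2 higher genes among 14.

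Markers of other cell types moved in both directions. Of 26 tested myeloid markers, 14 fell and 1 rose, with a median log2 fold change of -1.37 (Fisher's exact test, adjusted p = 1.12e-11). Counts adjusted over the list alone were 16 lower and 1 higher. The 9 called genes with at least 40 FPKM in wild-type cells, singled out after their values were seen, lay between -2.24 and -1.96, with a mean of -2.04 ± 0.09 (SD across 9 genes). Lyz2, encoding lysozyme, fell 4.14-fold from 518 to 125 FPKM, and the granule protein gene Ltf 4.28-fold from 218 to 50.9 FPKM. Together the 9 genes made up 1.87% of all FPKM in wild-type and 0.473% in Hdac3-deleted cells. Mpo, a primary granule gene, fell 1.97-fold from 10.3 to 5.26 FPKM, and Elane, Prtn3 and Ctsg did not pass the test. Cd14, at 2.94 FPKM or less, rose 4.87-fold, and Tyrobp, at 1185 and 1400 FPKM, did not pass the test. Ly6c2, Fcer1g, Cybb and Ccr2, all above 40 FPKM in wild-type cells, did not pass it either. Ly6c2 is also a member of the plasmacytoid dendritic cell list below. In which cells of the gate these genes were made was not tested.

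Plasmacytoid dendritic cell markers were abundant in both genotypes, with Siglech at 420 and 590 FPKM and Bst2 at 578 and 670 FPKM. None of the 19 tested genes changed, all 19 had positive fold changes, from 0.14 to 0.59 on the log2 scale, and their median of 0.34 was at percentile 99.99 of matched random lists. Among 25 T, NK and innate lymphoid markers, Tcf7 rose 1.57-fold and Eomes 1.51-fold, and the median was 0.24. Of 8 tested erythroid markers, Car2 fell 2.07-fold to 26.3 FPKM.

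Immediate early and stress genes had 27 tested members, of which 9 fell and 1 rose, with a median log2 fold change of -0.46 (Fisher's exact test, adjusted p = 1.33e-05). Besides Fos and Fosb, the heat shock genes Hspa1a and Hspa1b fell 6.78-fold and 4.97-fold, both from under 5 FPKM. Counts adjusted over the list alone were 13 lower and 2 higher. These genes were lower in the same samples in which the myeloid genes were lower.

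**Figure D3:**
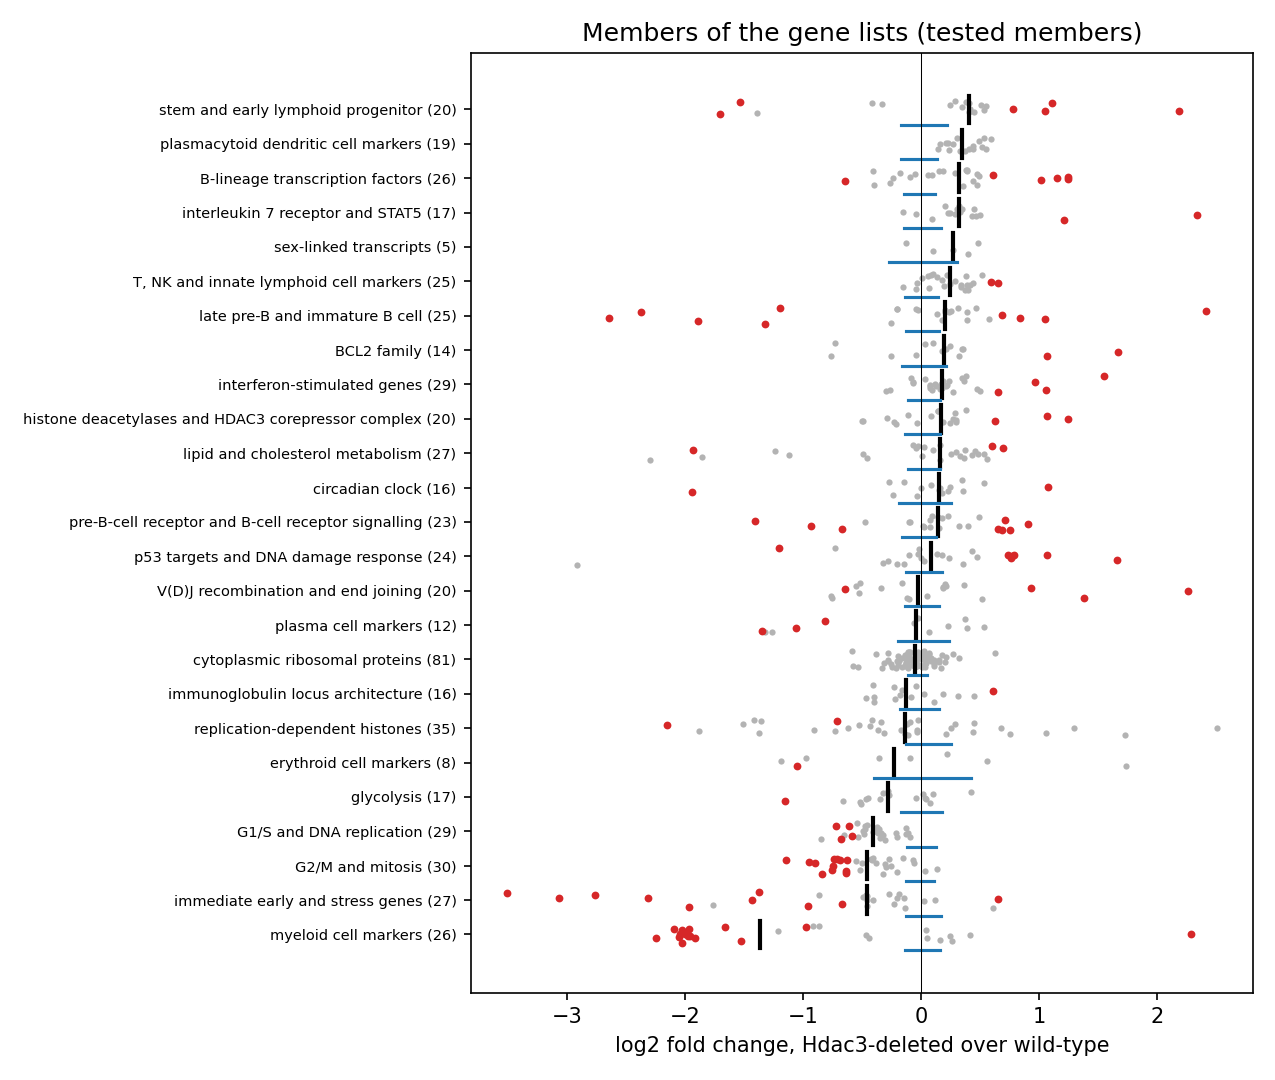
Log2 fold change of Hdac3-deleted over wild-type cells for the tested members of 25 gene lists, 1 point per gene, with the number tested in parentheses. Red points have a deposited q under 0.05, black bars are medians, and blue lines span the middle 95% of medians of 10000 random lists matched on expression; the myeloid median lies at -1.37 and the stem and early lymphoid progenitor median at 0.40.

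Histone deacetylase and corepressor genes included 3 higher genes of 20, namely Hdac11 at 2.36-fold, Hdac7 at 2.09-fold to 103 FPKM and Tbl1x at 1.54-fold (Fisher's exact test, adjusted p = 0.0675). Of 29 interferon-stimulated genes, 4 rose, Xaf1 2.93-fold, Rtp4 2.08-fold, Gbp2 1.95-fold and Gbp3 1.57-fold. Their enrichment passed narrowly (Fisher's exact test, adjusted p = 0.0416) and was 0.0532 with genes of at least 1 FPKM alone. In lipid and cholesterol metabolism, the sterol exporter Abcg1 rose 1.62-fold and the desaturase Scd2 1.51-fold, while Scd1 fell 3.82-fold from 11.6 to 3.03 FPKM. The median of the 27 lipid genes was 0.16 and the mean -0.14. Among 16 clock genes, Arntl rose from 74.7 to 157 FPKM and Bhlhe41 fell 3.84-fold. None of 81 cytoplasmic ribosomal protein genes changed in the authors' Cuffdiff test, with a median of -0.05. For the remaining lists, the counts adjusted over the list alone were 2 higher and 0 lower for interleukin 7 receptor and STAT5, 1 and 5 for plasma cell markers, 0 and 4 for glycolysis and 0 and 1 for histones. They were 2 higher and 1 lower for the BCL2 family, 3 and 0 for histone deacetylases, 4 and 0 for interferon-stimulated genes, 3 and 3 for lipid metabolism and 1 and 1 for the clock. They were 0 and 2 for erythroid markers, 2 and 0 for T, NK and innate lymphoid markers, 1 and 0 for locus architecture, and 0 in both directions for plasmacytoid dendritic cell markers, ribosomal proteins and sex-linked transcripts. Neither Xist, at 32.1 and 29.3 FPKM, nor the Y-linked Eif2s3y, at 40.7 and 49.1 FPKM, changed among the 5 sex-linked transcripts, and both were present in both genotypes.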

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

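Of the tests in this part, the expected ratio of the further neutrophil genes was written before their values were seen; all the others were chosen after the results they bear on, and that of the scaling replaced an earlier one whose outcome centring fixes. Outside the tested genes, 49 entries reached at least 5 FPKM in a genotype without a test. The entry naming both Gm9846 and Rps27 was 1889 FPKM in wild-type and 934 FPKM in Hdac3-deleted cells. Rps27, with an entry of its own that shares the locus, was 2548 and 3931 FPKM and did not pass the test.

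The 9 called myeloid genes with at least 40 FPKM in wild-type cells, picked after their values were seen and led by S100a8 and S100a9, fell about 4-fold. Tyrobp, Ly6c2, Fcer1g, Cybb and Ccr2 also exceeded 40 FPKM but were not called, with log2 fold changes from 0.04 to 0.41. Ly6c2 is in the plasmacytoid dendritic cell list as well, and whether these genes were made in myeloid cells here was not tested. The granule genes outside these 9 included Mpo, 1.97-fold lower, and Pglyrp1, at -1.21 on the log2 scale, both past the test, and Elane, Prtn3 and Ctsg at 2.31-fold, 1.83-fold and 1.89-fold without passing it. A smaller share of neutrophil RNA in the Hdac3-deleted samples was expected to lower 14 further neutrophil genes with at least 5 FPKM by 1 ratio, with a median log2 fold change between -2.4 and -1.6 and an interquartile range under 0.6. The median was -1.10 and the interquartile range 1.19, so this expectation failed, with Cd177 at -1.67 and Cyp4f18 at 0.61. Of the 14 genes, 9 were called lower, while Itgb2 and Alox5ap, at 97.6 and 164 FPKM in wild-type cells, lay at 0.10 and 0.12. A smaller share alone does not give these values if each gene is made only in neutrophils, which was not shown here. The test therefore cannot exclude a smaller share. Whether a smaller share holds for the 9 abundant called myeloid genes, or together with expression in other cells of the gate, was not tested. The authors' scaling does not account for a difference between gene groups if it is 1 factor per genotype, and the median of the 26 further neutrophil genes lay -1.52 log2 units from that of all genes with at least 1 FPKM in both genotypes.

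Recombinase and progenitor transcripts rose, with Rag1, Rag2, Dntt, Kit, Igll1 and Vpreb1 as the genes examined. A lower share of another cell type would raise all remaining transcripts alike, and the highest of the 19 plasmacytoid dendritic cell markers lay at 0.59 on the log2 scale. For Rag1 and Kit, the lower bounds from the authors' test statistics were 0.72 and 0.87. They were adjusted over all tested genes because the 6 were picked for having risen. If plasmacytoid cells kept their ratio to B-lineage cells, this argues against such a lower share as the whole cause for these 2. The marker level of 0.59 has no bound of its own. The other 4, with a median of 0.82, stay open. The rule behind this reading was rewritten repeatedly after the values were known. A larger share of pro-B cells within the gate may account for part of the rise, and an effect of genotype on transcription stays open and untested. The 6 genes spanned 1.60 log2 units, which leaves this open, because sorted stages that would show where each is expressed were not analysed here.

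Of 27 immediate early and stress genes, with a median of -0.46 on the log2 scale, 9 fell, 1 rose and 17 did not pass the test; the 9 that fell, selected by that result, had a median of -1.97. A smaller share of neutrophil RNA, whose expected ratio failed above, remains a candidate cause here. The B220+CD43+ gate marks early B-lineage cells, and whether neutrophils passed the sort was not measured. Losing neutrophil RNA cannot lower a gene by more than the neutrophil share falls, but the answer depended on the bound. 3 bounds were tried after the values were seen. With the lowest of all tested myeloid and neutrophil genes, -3.62, 0 of the 9 fell further. With the lowest of those with at least 5 FPKM in wild-type cells, -2.24, 4 did, namely Fosb, Fos, Hspa1a and Hspa1b. Hspa1a and Hspa1b were themselves under that minimum, at 1.57 and 3.67 FPKM in wild-type cells. With the 5th percentile of the 14 neutrophil genes, 5 of the 9 fell further. Handling of the tissue before the sort may also contribute, as 2 of 5 heat shock genes fell, and without values per library neither can be told apart from genotype.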

How the results depend on the processing

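The normal approximation to the test statistic, and counts without neutrophil genes, shared loci or genes in several lists, were chosen after seeing the data. Against 356 higher and 525 lower genes, a q threshold of 0.01 gave 189 and 345, a minimum of 1 log2 unit gave 130 and 296, and the normal approximation gave 136 and 335. Of its 471 calls, 428 were among the 881. At a q threshold of 0.01, the adjusted p for enrichment (Fisher's exact test) rose to 0.769 for pre-B-cell receptor signalling and fell to 0.0193 for V(D)J recombination. With genes of at least 1 FPKM alone it was 0.0751 for late pre-B genes among lower genes and 0.0532 for interferon-stimulated genes among higher genes. With a pseudocount of 1 FPKM the median of the further neutrophil genes moved from -1.50 to -1.04, as a pseudocount shrinks low genes. Within their bootstrap intervals, the basophil and mast cell median moved from -1.22 to -0.54 with that pseudocount and to -0.66 with genes of at least 1 FPKM. The histone median moved from -0.13 to -0.07 with the pseudocount. The erythroid median moved from -0.23 to -0.09 with the pseudocount and to -0.38 with genes of at least 1 FPKM. Without genes in other lists, the p53 median moved from 0.08 to 0.03 and the BCL2 family median from 0.19 to 0.10. With genes of at least 1 FPKM the p53 median was 0.13. The same pseudocount shrank the log2 fold change of 16 of 106 named genes by more than 1.5 times, all listed below 10 FPKM, among them Cr2 from -2.37 to -0.48, Gata2 from -1.54 to -0.40, Hspa1a from -2.76 to -1.06 and Egfl6 from -5.22 to -2.66. Apart from the thresholds themselves, the cause was not tested. Of all values compared, 353 were labelled the same, 9 weaker, 1 stronger, 1 moved and 0 reversed. For counts of genes the same meant within 1.5 times, and for list medians it meant inside the bootstrap interval. For Hdac3 it meant an unchanged sign. Single genes such as Cr2 and Egfl6 kept the label despite the shrinkage above. A pseudocount cannot change the sign of a fold change, so for single genes the label shows little. Of the 353, 137 came from centring, which moved every fold change by only 0.02 log2 units and left the calls unchanged. Without the myeloid and further neutrophil genes, 355 were higher and 494 lower. No paired analysis was possible because the table gives 1 value per genotype, although the labels number the libraries 1 and 2 in both. For the same reason leaving out a replicate and limma were not run. The comparison of DJ-proximal with DJ-distal V genes was not run either, since no V gene entries were used here. Unknown depth limits what can be said of low genes.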

Other observations

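The lists in this part were added after the main results were seen. The test of the further FoxO target genes, and the expected ratio of the further neutrophil genes given above, were written before their values were looked at. Of 13 tested basophil and mast cell genes, 4 were lower and 1 higher in Hdac3-deleted cells (Fisher's exact test for lower genes, adjusted p = 0.00462). Their median log2 fold change was -1.22, with a bootstrap interval from -2.26 to 0.01. That median was -0.66 with genes of at least 1 FPKM alone and -0.54 with a pseudocount of 1 FPKM. The basophil protease Mcpt8 fell 6.22-fold from 9.05 to 1.45 FPKM and Prss34 4.88-fold from 9.03 to 1.85 FPKM. Hdc, which makes histamine, fell 3.24-fold and the chemokine Ccl9 1.96-fold. This list was written because Mcpt8 and Prss34 had been seen to fall, and both count toward its test. The list is therefore not independent evidence of its direction. Of 26 tested further neutrophil genes, 17 fell and 0 rose, with a median of -1.50. Il1b fell 5.53-fold, Ceacam10 5.06-fold, Asprv1 3.87-fold and Mmp25 3.56-fold, all from under 5 FPKM.

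As Foxo1 rose 2.03-fold, a hypothesis was that FoxO1 activity rose with its transcript. Of 20 further FoxO target genes, left free of targets already seen to change, 2 rose, Tsc22d3 1.68-fold to 127 FPKM and Tnfsf10 1.60-fold to 20.9 FPKM. The median log2 fold change was 0.25, at percentile 99.9 of matched random lists, but enrichment among higher genes did not pass (Fisher's exact test, p = 0.107, adjusted p = 0.214). Of the 2 criteria set beforehand, the median met its own and the enrichment fell short. The share called higher was 10%, against 2.81% of all tested genes. Plasmacytoid dendritic cell markers had a median of 0.34, so the hypothesis remains undecided.

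A strain segment carried with the targeted allele would give changed genes near Hdac3 on chromosome 18. Within 10 Mb, 7 of 107 tested genes were called, or 6.54%, against 6.94% elsewhere (Fisher's exact test, two-sided p = 1), which argues against such a segment as a wide source of calls. The 7 include Prelid2, from position 41875696, and Cd14, from position 36725067, which rose 4.55-fold and 4.87-fold. A count of calls cannot tell whether single genes such as these changed through a segment near Hdac3.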
